A study of Homo sapiens with 4 samples.

How the data were processed

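RNA was measured by sequencing in 4 libraries of NCI-H1792, also written H1792, an established human lung cancer cell line. Per the labels' protocols, cells carried either a lentiviral short hairpin against green fluorescent protein (shCtrl, 2 libraries) or a hairpin against PAF (shPAF, 2 libraries), were grown in RPMI medium with fetal bovine serum, and RNA was extracted with a Qiagen RNeasy kit. PAF is the product of the gene PCLAF, also written KIAA0101. Groups and replicate numbers were taken from the sample titles, and the lentivirus entry of each sample gave the same group. The source name reads shPAF for all 4 samples and was not used for grouping. The replicates are called biological in the series' design text; whether they came from separate transductions or separate days is not given in the sources used here, so the p-values measure the spread between these samples. No batch is named in the labels, and a difference in handling between the groups therefore cannot be told apart from the hairpin.

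The authors deposited 1 table of FPKM values (fragments or reads per kilobase of gene model and per 1000000 reads) with 48162 Ensembl gene identifiers and 1 column per library. TopHat2 and the genome build GRCh37 (hg19) are named, per the submitters' processing notes. The version of the aligner, the program that counted reads, the annotation release, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands could have been mixed. Reads shared between near-identical genes could also have been split or lost, so levels of HLA genes, HSPA6 and HSPA1A, ribosomal protein genes, FTH1 and mitochondrially encoded genes are less certain than others.

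Gene symbols were matched by identifier to a current symbol table (33626 identifiers) and otherwise to GENCODE release 29 (11716), leaving 2820 without a symbol. GENCODE 29 is built on GRCh38. It was used for names, gene types, gene lengths, GC content and the location of PCLAF, and no coordinate was converted. GC content was that of the longest transcript. For coding and untranslated parts it was that of the longest transcript with a coding region. Of the 48162 identifiers, 18786 were listed at 0 in all 4 libraries. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 12673 in all, of which 12383 (97.7%) had a symbol and a GC content.

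Depth was worked out from the FPKM values themselves. A read count multiplied by a fixed factor per library and gene length gives the FPKM, so the library totals were solved from single-exon genes and the counts and gene model lengths of the other genes were then searched. All 12673 tested genes gave whole reads in all 4 libraries at a tolerance of 0.01 (100%), against 0.85% of 2000 genes when the totals were shifted on purpose. On simulated data, 95.3% of 2571 genes returned the exact reads. Between replicates, chi-square values of these reads averaged 22.5 per gene for shCtrl and 10.5 for shPAF, so neither group holds 1 library listed again under another name. Intervals on reads are exact Poisson intervals at the 95% level and cover counting error only.

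The comparison of shPAF with shCtrl was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the variance prior, 2 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. An exact permutation test of 2 against 2 samples cannot give a p below 0.33, so none is reported. On data simulated for this comparison over 12208 genes, the fit recovered 66 of 100 genes changed 2-fold and 94 of 100 changed 4-fold. There were 7 calls among 12008 unchanged genes, and 1 of 100 random lists reached p under 0.05. Only 200 simulated genes were changed, each gene varied independently, and no trend with GC content or shift of most genes was put in. The simulation therefore does not show how many false calls of genes or lists such features would give.

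Gene lists, 27 in number, were fixed before the data were examined, together with the tests and the rule for named genes. The 24 lists with at least 5 genes tested were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 24. Camera was repeated with a correlation estimated from the residuals, and fry and camera on ranks were also run. The rule named PCLAF, the 12 called genes with the largest rise and the 12 with the largest fall in fitted log2 fold change (leaving out small RNAs and clone names), and up to 4 called members of each list with the largest change. Other members are named only where 6 or fewer of a list went one way or missed the threshold, and these were chosen after their values were seen. Single values of a few list members are not reported here. A further 6 gene groups, described among the other observations, were also chosen after values were seen.

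Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median-centring, quantile normalization, factors from a trimmed mean of M-values, other variance priors, stricter thresholds, a replicate block and leaving out each library in turn. After the data had been seen, 2 more were added: removal of a trend with GC content and gene model length from each library by splines with 5 degrees of freedom, and limma's voom on the recovered reads. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.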

Results

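To learn which transcripts differ when PAF is depleted in lung cancer cells, RNA of H1792 cells carrying a hairpin against PAF (shPAF, n = 2) was compared with RNA of cells carrying a control hairpin (shCtrl, n = 2). H1792 is a human lung cancer cell line. PAF, encoded by PCLAF, binds PCNA, the sliding clamp of DNA replication. The FPKM values corresponded to totals of 27333757 and 27039996 reads in the shCtrl libraries and 26166700 and 28016856 in the shPAF libraries. Recovered reads of listed genes added up to 98.0% to 98.3% of these totals. That sum can fall short, because the search kept the smallest gene model length giving whole reads where the annotated length failed. At least 1 FPKM was reached by 12797 and 12957 genes in shCtrl and by 11294 and 11405 in shPAF. Pearson correlations across genes on the log2 scale were 0.99 between the shCtrl and 0.996 between the shPAF replicates, and 0.745 to 0.764 between libraries of different groups.

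PCLAF itself was nearly absent from the shPAF libraries. The gene (ENSG00000166803) lies on chromosome 15 from 64364311 to 64387687 on the minus strand of GRCh38, as annotated by GENCODE 29. It was measured at 37.3 FPKM (1541 reads, 95% counting interval 35.5 to 39.2 FPKM) and 36.0 FPKM (1469 reads, 34.1 to 37.8) in shCtrl. The shPAF libraries held 0.101 FPKM (4 reads, 0.0276 to 0.259) and 0.0472 FPKM (2 reads, 0.0057 to 0.171). The ratio of reads, shCtrl over shPAF, was 500 with a 95% counting interval of 229 to 1363. In the limma fit, PCLAF fell by 5.13 on the log2 scale (SE 0.10, adjusted p = 8.74e-07).

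All 111 measured genes of the DNA replication and mitosis lists were lower in the shPAF libraries. TOP2A, the topoisomerase that untangles replicated chromosomes, went from 66.3 ± 9.06 FPKM (SD, n = 2) in shCtrl to 0.226 ± 0.0653 in shPAF, a log2 fold change of -5.77 (SE 0.12, adjusted p = 8.74e-07). MKI67, which encodes the proliferation marker Ki-67, fell from 45.9 ± 7.23 to 0.162 ± 0.0222 FPKM. RRM2, the regulated subunit of ribonucleotide reductase, fell from 123 ± 4.94 to 2.09 ± 0.0584 FPKM. At the other end LCN2, a secreted iron-scavenging protein of inflamed epithelia, rose from 62.5 ± 31.7 to 4548 ± 826 FPKM, the largest rise among named genes on the log2(FPKM + 1) scale (log2 fold change 6.25, SE 0.32, adjusted p = 2.92e-06). GDF15, a cytokine released by stressed cells, rose from 3.51 ± 1.66 to 203 ± 2.10 FPKM.

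The other genes with the largest falls included many known from mitosis and cytokinesis. NUSAP1 (log2 fold change -5.60), BUB1 (-5.15) and DLGAP5 (-4.92) act at the mitotic spindle. ANLN (-5.44), CEP55 (-5.30), KIF20A (-4.94) and KIF23 (-4.91) act in cytokinesis, and ARHGAP11A (-5.05) fell with them. In these 8 genes the adjusted p was 8.74e-07 in the limma fit.

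The other large rises were of genes with varied known functions. PIGR, which carries antibodies across epithelia, rose from 0.405 ± 0.185 to 43.6 ± 5.58 FPKM (log2 fold change 4.99). The chemokine CX3CL1 (4.41), the adhesion molecule ICAM5 (4.10), the amino acid oxidase IL4I1 (4.07) and ICOSLG (3.98), a ligand of T cells, rose as well. HLA-B, an antigen-presenting molecule, rose from 11.7 ± 1.5 to 214 ± 3.21 FPKM (4.08), with the reservation that related HLA genes share reads. The heat-inducible chaperone gene HSPA6 differed between the shPAF replicates (59.8 ± 30.9 FPKM against 0.681 ± 0.132 in shCtrl, 5.08), and it has close relatives. CACNA1S, a muscle calcium channel subunit, rose from 0.104 ± 0.0219 to 33.2 ± 6.58 FPKM (4.94). ASB2, part of a ubiquitin ligase (4.41), and ASS1, an enzyme of arginine synthesis (4.13), completed the 12.

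**Figure D1:**
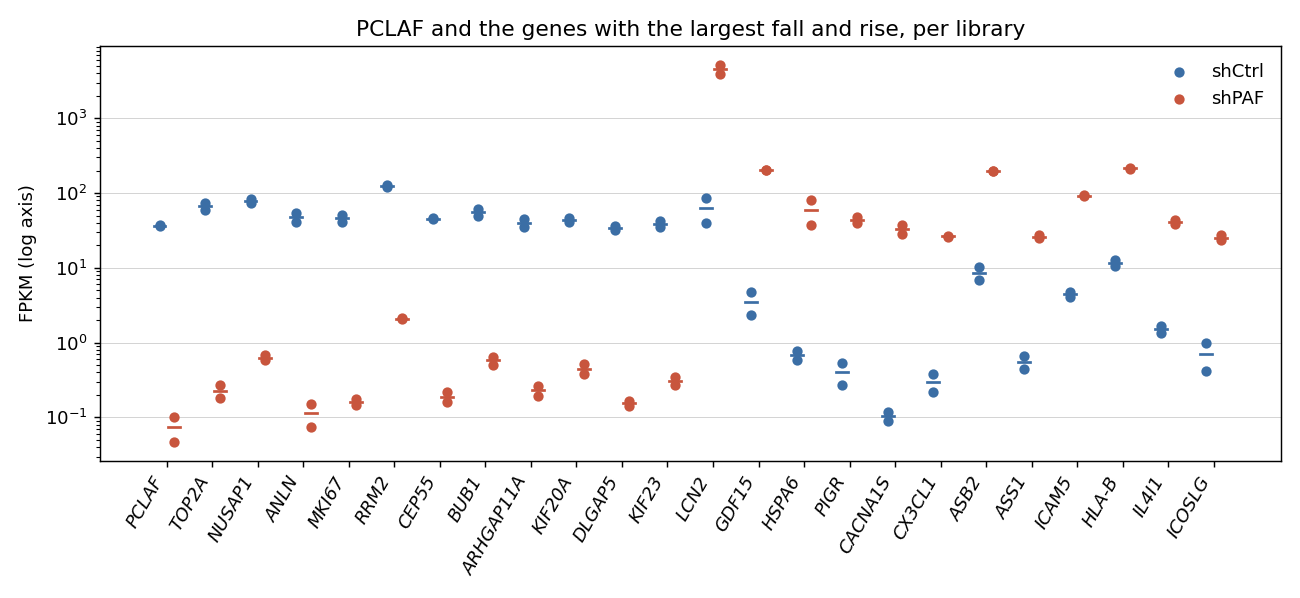
FPKM on a log axis of PCLAF, of the 11 other genes with the largest falls and of the 12 genes with the largest rises, with points for single libraries (blue shCtrl, red shPAF) and bars for the mean of 2 libraries. PCLAF sat at 37.3 and 36.0 in shCtrl against 0.101 and 0.0472 in shPAF, and no gene shown had overlapping groups.

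Of 12673 genes tested, 10436 (82.3%) were called by limma, 3806 higher and 6630 lower in shPAF. On the log2(FPKM + 1) scale, at least 2-fold changes were called higher for 1493 genes and lower for 4308. At least 10-fold changes on that scale were called for 26 and 164. These counts miss large changes of genes with low FPKM. BRIP1, for example, fell from 9.23 to 0.0862 FPKM (log2 fold change -3.23) and is not counted as 10-fold. The libraries of the groups did not overlap for 11548 genes (91.1%), where chance gives 33.3%. The median of all genes was -0.39, so the split between directions depended on scaling. Of the called genes 36.5% were higher as deposited, but 58.5% after median-centring, 52.5% after quantile normalization, 50.3% with factors from a trimmed mean of M-values and 50.5% after removal of the GC and length trend, which moved that median to 0.27, 0.08, 0.02 and 0.01. In the same order, these settings turned the sign of 1219, 873, 422 and 2733 of the called genes and called 346, 173, 19 and 1372 of them in the other direction, so the direction of single genes depended on these settings, also for some that changed over 2-fold as deposited, such as ETV1 (-1.54 as deposited, 0.09 with the GC and length trend removed).

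Fold changes followed the base composition of the genes. Across 12383 genes, which are not independent replicates, the Spearman correlation of fold change with GC content was 0.711, and with gene model length -0.316. The difference between replicates correlated with GC content at -0.064 in shCtrl and 0.057 in shPAF. Genes with 26.5% to 38.4% GC had a median log2 fold change of -1.75, those with 61.4% to 74.5% GC a median of 0.80. For this reason the median of each called list is also given with the GC and length trend removed, a setting chosen after the data were seen.

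**Figure D2:**
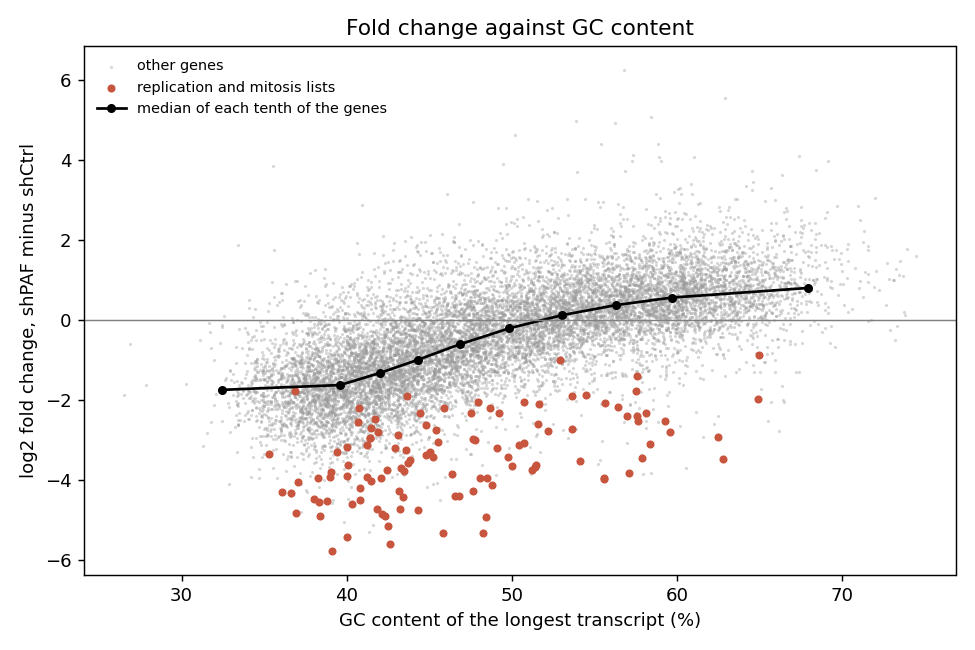
Log2 fold change, shPAF minus shCtrl, against the GC content (%) of the longest transcript, with the 111 genes of the replication and mitosis lists in red, other genes in grey and black points for the median of each of 10 equal groups of genes. Medians ran from -1.75 at the lowest to 0.80 at the highest GC content, and the red points lay below 0 over the whole range.

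All measured genes of the replication and mitosis lists fell. The 57 genes of the G1/S transition and DNA replication had a median log2 fold change of -2.81, and 57 were lower over all genes tested and 57 when adjusted over the list alone. Besides RRM2, the largest falls were in FANCI (-4.42) and RAD51AP1 (-4.31), both of DNA repair, and DTL (-3.96), a substrate receptor that acts on replication factors. The list differed from other genes by camera in limma at adjusted p = 1.72e-11 (0.724 as adjusted p with an estimated correlation). The 54 genes of G2/M and mitosis had a median of -4.01, with 54 lower over all genes and 54 adjusted over the list alone (camera adjusted p = 2.74e-13, but adjusted p = 0.724 with an estimated correlation). With the GC and length trend removed the medians were -2.31 and -3.33.

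Regulators of these genes and the repair machinery were also lower. Of 13 subunits of the DREAM and MuvB complexes, which switch cell cycle genes off and on, 11 fell and 0 rose, counts that were 11 and 0 when adjusted over the list alone, with a median of -1.58. FOXM1 fell from 49.1 ± 4.04 to 2.20 ± 0.136 FPKM and MYBL2 from 68.7 ± 14.1 to 4.29 ± 0.129, both of them activators that join MuvB. FOXM1 was also a member of the G2/M list and RBL1 of the G1/S list, so these lists are not separate evidence for them. RBL1 (-3.17) and LIN9 (-2.56) fell as well, whereas E2F4 (-0.05) and E2F5 (-0.07) did not pass the test. The DREAM and MuvB list was called at adjusted p = 0.0116 by camera, with adjusted p = 0.724 with an estimated correlation. With the GC and length trend removed it was 0.0906, when the median of the list was -0.55 with 2 higher and 8 lower. Of 29 DNA repair and Fanconi genes, 26 fell, 1 rose (FANCE, 0.67) and FANCC (-0.25) and RAD51D (-0.09) were not called, with the same 26 and 1 adjusted over the list alone. Examples were the recombination gene XRCC2 (-3.74), the double-strand break sensor MRE11 (-3.60), FANCB (-3.47) and the helicase BRIP1 (-3.23). The median was -2.54, or -1.01 without the trend (camera adjusted p = 3.32e-05, adjusted p = 0.724 with an estimated correlation).

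Genes of the ATF4 response and of endoplasmic reticulum folding were mostly higher in shPAF. Of 27 genes of amino acid shortage and the transcription factor ATF4, 20 rose and 4 fell, and as many when adjusted over the list alone, with a median of 1.44 (1.28 without the trend). TRIB3, a pseudokinase induced by ATF4, rose from 30 ± 9.75 to 269 ± 10.7 FPKM, and DDIT3, the stress factor CHOP, from 17.3 ± 6.64 to 122 ± 0.822. CHAC1 (2.82), which degrades glutathione, and DDIT4 (2.78), an inhibitor of mTOR, rose too. SLC7A11, the cystine transporter (-2.45), ALDH1L2 (-1.08), CEBPG (-0.72) and PSAT1 (-0.42) fell, and with the GC and length trend removed 24 of the list were higher and 1 lower. Camera gave adjusted p = 1.03e-05, and adjusted p = 0.724 with an estimated correlation. Of 19 chaperones and other folding genes of the endoplasmic reticulum, 13 rose and 5 fell, also 13 and 5 adjusted over the list alone, with a median of 0.93 (1.19 without the trend). HERPUD1 (1.97), CALR (1.80), SDF2L1 (1.62) and HSPA5 (1.46), the main Hsp70 of that compartment, rose. HSP90B1 (-0.78), CANX (-0.61), DNAJC3 (-1.13), SEL1L (-0.96) and EDEM1 (-0.83) fell. These falls depended on scaling, with 17 higher and 0 lower once the GC and length trend was removed, 14 and 1 after median-centring, 14 and 2 with trimmed-mean factors and 10 and 5 after quantile normalization. The list was called at adjusted p = 0.00351, but not with an estimated correlation (adjusted p = 0.786), after quantile normalization (0.261) or by fry (0.0867).

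NF-kB target, hypoxia and cholesterol genes were mostly higher as well. Of 23 inflammatory and NF-kB target genes, 16 rose and 4 fell, unchanged in number when adjusted over the list alone. The chemokine CCL20 rose from 17.0 ± 6.64 to 252 ± 30.8 FPKM, the adhesion molecule ICAM1 from 16.7 ± 3.24 to 230 ± 0.434 and the growth factor CSF2 from 129 ± 63.0 to 710 ± 4.41. BIRC3, an inhibitor of apoptosis (-2.90), IL1A (-0.87), TNFAIP3 (-0.65) and NFKB1 (-0.50) fell, and with the GC and length trend removed 18 of the list were higher and 2 lower. The median was 0.94 (0.95 without the trend) and camera gave adjusted p = 3.07e-04, with adjusted p = 0.738 with an estimated correlation and 0.0723 by fry. Of 30 hypoxia and glycolysis genes, 19 rose and 3 fell, again 19 and 3 adjusted over the list alone, with a median of 1.09 (0.94 without the trend, 0.57 after quantile normalization). CA9, a carbonic anhydrase induced by low oxygen, rose from 15.7 ± 0.763 to 161 ± 12.4 FPKM, followed by ALDOC (2.82), P4HA2 (2.80) and NDRG1 (2.76). KDM3A (-2.22), BNIP3L (-1.05) and LDHA (-0.54) fell, and with that trend removed 25 of the list were higher and 1 lower. The camera adjusted p was 1.44e-05, and the adjusted p was 0.724 with an estimated correlation. Of 22 cholesterol synthesis genes, 14 rose and 5 fell, 14 and 5 also when adjusted over the list alone, with a median of 0.76 (0.85 without the trend). Among those that rose were TM7SF2 (3.34), DHCR7 (1.87) and their regulator SREBF2 (1.85), and among those that fell were HMGCS1 (-1.54), STARD4 (-1.5), SC5D (-1.44) and IDI1 (-0.82). With the GC and length trend removed 17 of the list were higher and 1 lower, and after median-centring 16 and 3. Camera called the list at adjusted p = 0.00227, and gave adjusted p = 0.724 with an estimated correlation.

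Cytosolic ribosomal protein genes rose together and took a larger share of the reads, 14.1% and 13.9% in shPAF against 5.17% and 5.73% in shCtrl. Of 73 genes, 65 rose and 4 fell (66 and 4 adjusted over the list alone), with a median of 1.30 (1.39 without the trend). After quantile normalization the median was 0.63, with 53 higher and 9 lower. RPL36 rose by 2.38, RPL10 by 2.11, RPL8 by 2.04 and RPL37A by 1.95 on the log2 scale. RPL17 (-1.0), RPL26 (-0.95), RPS10 (-0.41) and RPL6 (-0.37) fell, the first 3 from under 10 FPKM. Many ribosomal protein genes have processed pseudogenes with which reads can be shared. The camera adjusted p was 2.25e-17, with adjusted p = 0.724 with an estimated correlation.

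**Figure D3:**
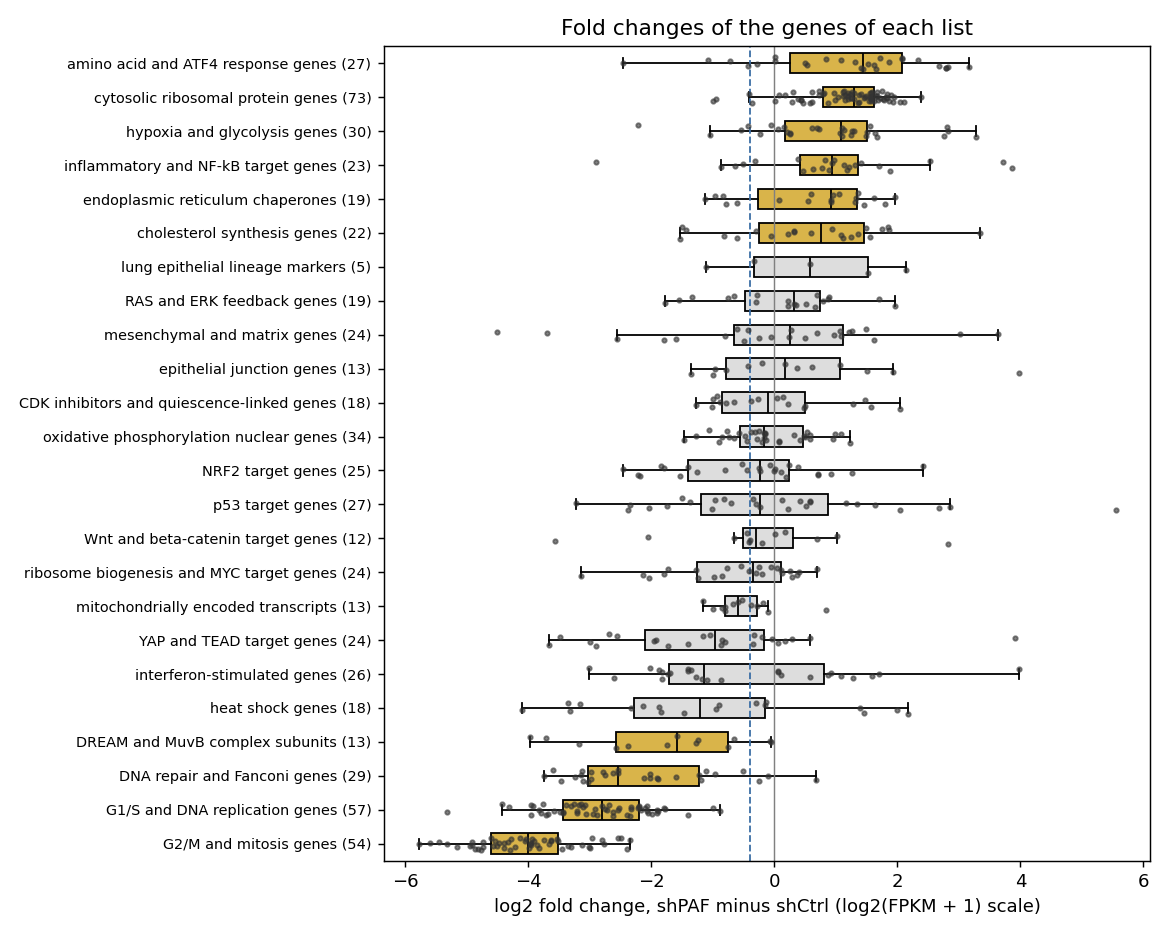
Log2 fold change, shPAF minus shCtrl, of the genes of 24 lists, with a box for quartiles, a line for the median, whiskers for the range within 1.5 box lengths and points for single genes (number in brackets). Yellow lists were called by camera (10 lists) and grey ones were not, the dashed line is the median of all genes (-0.39), and medians of called lists kept their sign under each scaling.

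Lists of genes that restrain the cell cycle, of p53 targets and of Wnt targets were not called by camera. CDKN1A, the inhibitor p21, rose from 20 ± 0.993 to 85.6 ± 0.0783 FPKM (2.04). CDKN1C (1.57), YPEL3 (1.48), BTG1 (1.28), CDKN2D (0.50) and CDKN1B (0.48) also rose. Of the 18 CDK inhibitors and quiescence-linked genes, 6 rose and 8 fell, 6 and 8 also when adjusted over the list alone, and the camera adjusted p was 0.433. These counts depended on scaling, with 10 higher and 1 lower after median-centring, 9 and 1 after quantile normalization, 9 and 6 with trimmed-mean factors and 8 and 3 with the GC and length trend removed. Of 27 p53 target genes, 11 rose and 13 fell (adjusted over the list alone 11 and 13, camera adjusted p = 0.433), against 16 higher and 9 lower after median-centring. Besides GDF15, the cell death gene BBC3 (2.86) and SESN2 (2.67) rose, while PLK2 (-3.22) fell. Of 12 Wnt and beta-catenin target genes, 3 rose and 6 fell, and as many adjusted over the list alone (camera adjusted p = 0.836), but after median-centring 8 were higher and 2 lower. Fry called this list, in the direction down (adjusted p = 0.00822). NKD2 (2.82), a Wnt antagonist, CD44 (1.02) and MYC (0.69) rose, whereas the secreted antagonists DKK1 (-3.56) and NOTUM (-2.06) fell, as did CCND1 (-0.66), EPHB2 (-0.45), ZNRF3 (-0.40) and TCF7 (-0.40). The medians of these 3 lists were below 0 as deposited (-0.11, -0.23 and -0.30) and above 0 after median-centring (0.55, 0.43 and 0.36), quantile normalization (0.38, 0.32 and 0.27) and trimmed-mean factors (0.34, 0.25 and 0.10). With the GC and length trend removed they were 0.21, 0.12 and -0.36, the Wnt list with 3 higher and 7 lower. Camera, which compares a list with other genes, pointed up in each as deposited, and the mean was 0.03 for the CDK inhibitor and p53 lists.

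Several other lists held both rises and falls, often in unequal numbers, and were not called by camera as deposited. Of 26 interferon-stimulated genes, 8 rose and 15 fell (8 and 15 adjusted over the list alone, camera adjusted p = 0.879, median -1.14). After median-centring 11 were higher and 14 lower with a median of -0.48, and with the GC and length trend removed 7 and 6 with a median of -0.08. BST2, which tethers virus particles, rose (3.97), while SAMD9 (-3.01) and IFI44 (-2.61) fell. Of 24 YAP and TEAD target genes, 17 fell and 2 rose, 17 and 2 also adjusted over the list alone, with a median of -0.96 and a camera adjusted p of 0.0864 (adjusted p = 0.724 with an estimated correlation). After median-centring 12 were lower and 9 higher (median -0.30), and after quantile normalization 14 and 7 (median -0.45). ANKRD1 (-3.67), MYOF (-3.47) and TEAD1 itself (-3.00) fell, against rises of IGFBP3 (3.91) and GADD45A (0.59). That list passed the threshold without a filter (adjusted p = 0.00469), on ranks (0.042) and with the GC and length trend removed (9.74e-04). Of 18 heat shock genes, 12 fell and 4 rose, 12 and 4 also adjusted over the list alone (camera adjusted p = 0.260, median -1.21, and 0.0102 without the trend), against 9 lower and 7 higher after median-centring. HSP90AA1 fell from 550 ± 43.9 to 31.1 ± 0.728 FPKM, with CHORDC1 (-3.34), HSPH1 (-3.32) and HSPA4L (-3.15), and HSPA1A (2.18), HSPB1 (2.00), HSPA1B (1.45) and DNAJB1 (1.40) rose. Of 19 RAS and ERK feedback genes, 10 rose and 7 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.0997), with DUSP5 (1.96) and FOS (1.71) among the rises. After median-centring 14 were higher and 3 lower, with trimmed-mean factors 12 and 3, after quantile normalization 10 and 5, and with the GC and length trend removed 10 and 3.

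The NRF2, oxidative phosphorylation, ribosome biogenesis and mitochondrial transcript lists were not called by camera as deposited. Of 25 NRF2 target genes, 6 rose and 11 fell, also 6 and 11 adjusted over the list alone (camera adjusted p = 0.958), but 14 were higher and 8 lower after median-centring and 12 and 9 with trimmed-mean factors. Fry called this list, in the direction down (adjusted p = 0.00376), where camera pointed up. TXNRD1, which keeps thioredoxin reduced, fell from 340 to 72.0 FPKM (-2.22) and GCLM (-2.18) fell, while the ferritin gene FTH1 rose (2.42). Of 34 nuclear genes of oxidative phosphorylation, 11 rose and 14 fell, and the same numbers adjusted over the list alone (camera adjusted p = 0.529), NDUFA1 (1.23) and COX4I1 (1.09) rising and UQCRC2 (-1.27) falling. After median-centring 22 of them were higher and 3 lower, and with trimmed-mean factors 18 and 7. Of 24 ribosome biogenesis and MYC target genes, 5 rose and 13 fell (5 and 12 adjusted over the list alone, camera adjusted p = 0.505). After median-centring 12 were higher and 7 lower, with trimmed-mean factors 9 and 9, and with the GC and length trend removed 2 and 14. NOP58 (-3.14), NOLC1 (-2.13), NCL (-2.03) and WDR12 (-1.80), which build ribosomes in the nucleolus, fell, while NOB1 (0.69), RRP9 (0.40), PES1 (0.37), FBL (0.29) and RRP12 (0.25) rose. Reads of all genes of the mitochondrial genome, not only those listed, made up 3.71% and 3.15% in shCtrl and 2.22% and 2.61% in shPAF. Of 13 mitochondrially encoded transcripts, 9 fell and 1 rose, 9 and 1 also adjusted over the list alone (camera adjusted p = 0.433). This fall depended on scaling, with 0 higher and 11 lower after quantile normalization, but 3 and 1 after median-centring, 2 and 2 with trimmed-mean factors and 2 and 0 with the GC and length trend removed. MT-ND4 fell by 0.997 on the log2 scale but lost its call after median-centring (adjusted p = 0.0611) and without the trend (0.0925). MT-ND3 rose by 0.84, and its sign turned after quantile normalization (adjusted p = 0.407). Medians of these 4 lists were below 0 as deposited (-0.23, -0.17, -0.35 and -0.59) and above 0 after median-centring (0.43, 0.49, 0.31 and 0.07), and with trimmed-mean factors those of the first 3 were too (0.24, 0.30 and 0.12). As deposited, camera pointed up for the NRF2 and oxidative phosphorylation lists.

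Matrix, junction and lineage genes changed singly. Of 24 mesenchymal and matrix genes, 12 rose and 8 fell, 12 and 8 also adjusted over the list alone (camera adjusted p = 0.127), and 15 were higher and 5 lower after median-centring. The collagen VI genes COL6A2 (3.63) and COL6A1 (3.02) rose, and THBS1, which encodes thrombospondin, fell from 114 ± 9.08 to 4.05 ± 0.147 FPKM, with POSTN (-3.69). Of 13 epithelial junction genes, 6 rose and 4 fell, as many as adjusted over the list alone (camera adjusted p = 0.260). The claudin genes CLDN3 (3.97), CLDN4 (1.93) and CLDN7 (1.5) rose with ELF3 (1.07), KRT18 (0.62) and KRT8 (0.37). CLDN1 (-1.35), EPCAM (-1.0), KRT7 (-0.96) and OCLN (-0.78) fell, CLDN1 turning to 0.05 without the trend (adjusted p = 0.684). Of 5 lung lineage markers tested, LAMP3 (2.14) and ABCA3 (1.53) of surfactant-secreting cells and MUC1 (0.58) rose and FOXA1 (-1.11) fell, while KRT5 (-0.33) was lower only when adjusted over the list alone (3 rose and 2 fell), with a camera adjusted p of 0.260. MUC1 lost its call without shCtrl replicate 2 (adjusted p = 0.0868) or shPAF replicate 1 (0.186) and turned to -0.63 without the trend. The median of the lung list turned likewise, from 0.58 to -0.63.

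Markers of leukocytes were scarce. Of 16 leukocyte markers only CD14 reached the filter, at 0.528 ± 0.307 FPKM in shCtrl and 2.28 ± 0.651 in shPAF (log2 fold change 1.10, adjusted p = 0.00144, or 0.063 without the trend, and 1 higher adjusted over the list alone). Of 17 fibroblast, endothelial and erythroid markers, 4 were tested. PDGFRB rose (0.97), LUM fell (-0.87, but 0.74 without the trend), and DCN (0.07) and PDGFRA (0.12) were not called, with 1 higher and 1 lower also when adjusted over the list alone. Of 3 neuroendocrine markers tested, ENO2 rose from 46.1 ± 4.81 to 244 ± 42.2 FPKM (2.37), DLL3 (1.22) rose and UCHL1 fell from 324 ± 5.29 to 269 ± 3.71 FPKM (-0.27), 2 and 1 also adjusted over the list alone. DLL3 lost its call without the trend (adjusted p = 0.0542). UCHL1 turned to 0.39 after median-centring and lost its call without shPAF replicate 1 (adjusted p = 0.187) or shPAF replicate 2 (0.146).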

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

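The settings with the GC and length trend removed and with voom were chosen only after the results had been seen. PCLAF kept its call and direction in every setting. Genes called ranged from 3275 to 3837 higher and from 6122 to 6614 lower when each library was left out in turn, where the lone library is assumed to vary like the other group. The replicate numbers were not shown to pair the libraries (correlation of deviations -0.048 over 2 pairs), and the replicate block gave 3814 higher and 6641 lower. Voom gave 3784 and 6601. Counts moved over 1.5 times with a filter of 5 FPKM (3987 lower, with fewer genes tested), median-centring (6232 higher), the trend removed (4218 lower) and a minimum log2 fold change of 1 (1493 higher, 4308 lower). Of 10210 calls tested again without the trend, 5775 remained and 1372 were called in the other direction.

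With an estimated correlation 0 of 24 lists were called, against 10 with the preset one. Adjusted p was 0.724 for 8 of these lists, 0.738 for NF-kB and 0.786 for endoplasmic reticulum chaperones. The estimated correlation was 0.574 for ATF4, 0.598 for NF-kB and 0.915 for these chaperones, against the preset 0.01. With 2 residual degrees of freedom it is poorly known. Some members did differ together between shCtrl replicates 1 and 2: TRIB3 (23.1 and 36.9 FPKM), HERPUD1 (28.2 and 47.5) and CCL20 (12.3 and 21.7). SLC7A11 of the ATF4 list went the other way (30.2 and 27.9). The p-values with the preset correlation may therefore be too small. Endoplasmic reticulum chaperones also lost the call after quantile normalization (0.261) and by fry (0.0867), NF-kB by fry (0.0723), and DREAM and MuvB without the trend (0.0906). The YAP list passed with no filter (0.00469), without the trend (9.74e-04), by fry (0.00376) and on ranks (0.042). Heat shock genes passed after quantile normalization (0.0253), without the trend (0.0102) and by fry (0.00822). Mitochondrial transcripts passed after quantile normalization (0.00343), ribosome biogenesis without the trend (0.00914) and by fry (0.0313), interferon-stimulated genes (0.0207) and lung markers (0.00822) by fry. Fry asks whether a list moves on balance, not whether it differs from other genes; for the other settings the cause was not tested. In 18 comparisons a list without a camera call turned direction. By fry the NRF2 (0.00376) and Wnt (0.00822) lists turned from up to down and passed, and the p53 (0.0933), mesenchymal (0.146) and oxidative phosphorylation (0.139) lists turned down without passing. None of the others passed. They were the NRF2 list with no filter (0.802), a filter of 5 FPKM (0.85), quantile normalization (0.355), the GC and length trend removed (0.713) and ranks (0.959), the Wnt list with a filter of 5 FPKM (0.76) and the trend removed (0.34), and oxidative phosphorylation after quantile normalization (0.408), all to down. Interferon-stimulated genes turned up with no filter (0.826), a filter of 5 FPKM (0.574) and the trend removed (0.956), where lung markers turned down (0.956) and mitochondrial transcripts up (0.574). Of the remaining comparisons of lists, 411 gave the same call and direction.

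Among single named genes, 1865 comparisons gave the same call, 15 lost it and 10 turned direction. The turns were UCHL1 after median-centring (adjusted p = 0.00368) and with trimmed-mean factors (0.0464), MT-ND3 after quantile normalization (0.407) and, without the trend, CLDN1 (0.684), MUC1 (0.0163), ETV1 (0.529), NDUFS1 (0.888), MT-ATP8 (0.0517), MT-ND4L (0.326) and LUM (0.00199). The cause was not tested. Depth limits PCLAF in shPAF, read from 4 and 2 reads, to a ratio between 229 and 1363.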

Other observations

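The 6 gene groups described first were chosen only after the results had been seen. Their camera p-values are therefore descriptive and cannot serve as tests. The tests of both sets of lists without the GC and length trend and of the PCLAF ratio were also chosen after that. The bounds for the tests of base composition and of leukocyte markers were written before those tests were run. They address patterns already seen in these results and were not part of the plan fixed at the start.

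Antigen presentation genes were higher in shPAF cells. Of 18 tested, 14 rose and 2 fell, with a median log2 fold change of 1.00 (camera adjusted p = 5.86e-05 over the 6 groups, adjusted p = 0.644 with an estimated correlation). Without the GC and length trend the median was 0.77, with 15 higher and 2 lower (3.74e-04). HLA-C rose from 121 ± 19.1 to 479 ± 13.1 FPKM, with the shared reads of HLA genes as a limit, and CD74, the invariant chain of class II molecules, rose from 1.03 ± 0.0975 to 17.2 ± 3.02. Among the class II genes of the group HLA-DMA rose (0.62), while HLA-DRA, HLA-DRB1 and HLA-DMB did not reach the filter, nor did CIITA. The immunoproteasome genes PSMB10 (1.71), PSMB9 (1.2) and PSMB8 (1.02) rose. TAP2 (-1.31), of the peptide transporter, and ERAP2 (-1.70), a peptide-trimming enzyme, fell. Lysosomal genes followed with 14 of 28 higher and 7 lower and a median of 0.29 (camera adjusted p = 0.00597, adjusted p = 0.644 with an estimated correlation), GAA (2.34), CTSD (2.19) and PSAP (1.99) leading. Without that trend 18 were higher and 8 lower, with a median of 0.60 (camera adjusted p = 0.0389). Of 10 complement genes, 5 rose and 5 fell (camera adjusted p = 0.309, but 0.0101 without the GC and length trend, when 7 were higher and 1 lower; with an estimated correlation, as deposited, adjusted p = 0.644). The secreted components CFD (2.98), C3 (2.91), C1R (2.84), C1S (1.45) and the inhibitor SERPING1 (0.57) were the ones that rose, and the membrane regulators CD59 (-1.27), CD55 (-1.11) and CD46 (-1.04) and CFI (-0.60) were among those that fell.

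Nuclear transport genes were lower. The group held receptors together with RAN (-0.80) and its binding protein RANBP1 (-1.12). Of 23 genes tested, 22 fell and TNPO2 (0.14) was not called, with a median of -1.91 (camera adjusted p = 5.86e-05, adjusted p = 0.644 with an estimated correlation). CSE1L, which recycles importin alpha, fell from 150 ± 18.5 to 5.63 ± 0.140 FPKM, XPO1, the main protein exporter, from 69.6 ± 5.25 to 4.05 ± 0.0454, and the importin KPNA2 fell by 3.93 on the log2 scale. Without the GC and length trend the median was -0.53 and 18 were lower. Of 8 subunits of the CCT chaperonin, which folds actin and tubulin, 6 fell, CCT7 rose (0.54) and CCT3 (0.05) was not called (camera adjusted p = 0.172, median -1.74). Without the trend 2 were higher and 5 lower, with a median of -0.80 (adjusted p = 0.0747). Of 11 proteasome core subunits 5 fell, PSMB5 (0.38) and PSMB7 (0.32) rose and 4 were not called (camera adjusted p = 0.764, median -0.21), and without the trend 4 were higher and 4 lower, with a median of 0.11.

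Fold changes followed GC content across genes, with genes poor in GC lower in shPAF. Given the GC content of the whole transcript, the coding part kept a partial Spearman correlation of 0.17 with the fold change and the untranslated parts one of 0.01, across genes. This lies between the bounds written for a bias acting on whole transcripts and for its absence, and since the groups may also have been prepared apart, such a bias and an effect of depletion cannot be told apart. The hypothesis that depletion itself lowered transcripts poor in GC therefore stays open and was not tested.

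Replication and mitosis genes fell together. With the GC and length trend removed their median was -2.71 (SD 0.95 over 111 genes, from -3.43, SD 1.04) and 110 of 111 were still called lower, which argues against the trend as the whole cause. PCLAF is itself a gene of dividing cells, and a stop of division could have lowered it with the others. Its ratio of 500 (229 to 1363) was exceeded by 1 of the 111 genes, CENPE at 1104, and 7 lay above the lower bound of the interval, so a direct effect of the hairpin on PCLAF and a loss of dividing cells cannot be told apart from RNA levels at this depth. An arrest of division after PCLAF depletion remains a hypothesis.

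The ATF4, NF-kB, hypoxia and chaperone lists were mostly higher, with 68 of their 99 genes called higher as deposited. As deposited, other stress and defence lists had more genes lower than higher (12 of 18 heat shock, 11 of 25 NRF2 and 15 of 26 interferon-stimulated genes lower). This turned for the interferon list with the trend removed (7 higher, 6 lower) and for the NRF2 list after median-centring (14 higher, 8 lower) and with trimmed-mean factors (12 higher, 9 lower). With the trend removed, the 99 genes had a median of 1.18 (SD 1.00, from 1.07, SD 1.27) and 84 were called higher, which argues against the trend as the cause. Leukocytes among the cells are unlikely as a source, since only 1 of 16 leukocyte markers reached 1 FPKM in both shPAF libraries and the median marker stood at 0.01 FPKM, with CD14 at 1.82 and 2.74 and PTPRC at 0 and 0.0067. Culture density, medium exhaustion and the hairpin's own effects were not tested and stay open beside a response of the cells to PCLAF depletion, which is a hypothesis from the same data.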
